A study of Mus musculus with 42 samples.

How the data were processed

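The series holds 42 2-colour oligonucleotide arrays of mouse RNA. In each array 1 channel held RNA of a skin or tumour and the other a universal mouse reference RNA, so the reference was common to all samples and belonged to no group. On the first array design lay 32 arrays with a group in their labels, 6 of normal skin, 10 of low-risk papillomas, 10 of high-risk papillomas and 6 of squamous cell carcinomas. On the second design lay 10 arrays of papillomas labelled as unknown.

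The deposited values are log2 ratios of the 2 channels, made by the authors from scanner data that were not analysed here. Per the labels the reference was in Cy5 and the sample in Cy3 on 31 of the 32 labelled arrays and the dyes were swapped on 1. The log base and the direction are not stated in the labels. Base 2 was taken because the largest size of a value was 15.02, and a scanner range of 16 bits rules out a natural or decimal log of that size. Cy5 over Cy3 is the likely direction, because 18 genes of skin had a median below 0 and 22 genes of internal organs a median above 0 on all 31 arrays with the sample in Cy3, while on the swapped array these medians were 2.46 and -0.14. All 10 arrays of the second design behaved like the 31. The authors' normalization and spot filters are not stated, and the medians of the deposited labelled arrays ran from -0.23 to 0.32. Their SD ran from 0.45 to 1.95, so the spread was not made equal.

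Values were turned to log2 of sample over reference by changing the sign of all arrays but the swapped one. The swapped array and another array held the same low-risk tumour and were averaged to 1 replicate by their labels, with r = 0.306 across probes between them, genes not being independent replicates. The swapped array correlated with the other arrays at 0.189 to 0.629, highest with low-risk papilloma 5, and arrays of 1 group and set at a median of 0.66, so the values leave its tumour in doubt. Its title and its source name give different numbers, as do those of low-risk papilloma 10, whose source name bears the number of the swapped array's title. Each array was then centred on its median. A probe was tested when it was measured in at least 3 replicates of every group and in at least 70% of the 31 replicates, and 1 probe per gene symbol was kept, chosen by the number of values, which gave 18904 probes, 13465 of them with a symbol. Probes were named from the platform's annotation, where 16076 of the first design had 1 symbol, 288 several and 5633 none, and probes with several or none were not named.

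Groups were compared with limma 3.58.1 in R 4.3.3, as 1 model of the 4 groups with moderated variances and Benjamini-Hochberg adjustment over all probes tested, at a threshold of 0.05, in 6 comparisons. The rule for naming genes, fixed before the data were examined, took the 10 largest rises and the 10 largest falls among called genes between tumour groups, and 6 of each against normal skin that were measured in every replicate of both groups and had a full gene name, and up to 4 members with the smallest p of each list that passed or had at least 3 members past the test. Of other lists that are described, up to 3 members with the smallest p are given. Gene lists, 30 in all with 10 to 57 tested members, were written before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes and again with a correlation estimated from the data, and with fry, which tests whether the genes of a set move on balance one way and does not set them against other genes. With the array set as a block, without the near-identical pair and after scale normalization, lists were tested only with camera at the preset correlation. Lists that the results leave out passed camera in no comparison. The score from normal skin to carcinoma was compared between papilloma groups with an exact 2-sided permutation test. Tables were made with numpy 2.4.6 and pandas 2.3.3.

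The fits were tested on simulated data with 18904 genes of which 200 changed. Limma recovered 70% to 90% of the genes with a log2 change of 2 and 19% to 34% of those with a change of 1, with 2 to 9 false calls in a comparison. The simulated values held no array sets and no correlation between genes, so these false calls need not hold for the real data.

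Numbers in the labels did not pair the samples: samples of different groups with the same replicate number correlated at a median r of -0.0245 over 37 pairs and those with different numbers at 0.01 over 317, across genes, after the group means were removed. Some tumours share a code in their labels, and the consensus correlation of these was 0.0135. Alternatives chosen before the data were examined were other scalings of the arrays, other filters and summaries of probes, other treatments of the swapped array, blocks by range of database number, by shared code and by replicate number, fits of only the groups compared, robust and weighted fits, and leaving out each replicate in turn. Fits within sets used 1 model of all combinations of group and set, so a single sample on 1 side had no spread of its own and was assumed to vary like the others. The array sets and the near-identical pair were seen in the data, and the alternatives with the set as a block, within sets and without the pair, the direction within a set of genes called from the other sets alone, and list tests after scale normalization, were chosen after seeing the data. The unlabelled papillomas were left out of all comparisons because no label gives their group, and only their scores are given.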

Results

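Gene expression was measured in normal skin and in skin tumours of mice given DMBA, which starts tumours, and TPA, which promotes them. Each RNA was hybridised on a 2-colour oligonucleotide array against one common reference, a universal mouse RNA pool. The tumours were papillomas, which are benign, of the groups labelled low-risk and high-risk, and squamous cell carcinomas, which are malignant. The labelled samples were 6 normal skins, 9 low-risk papillomas, 10 high-risk papillomas and 6 carcinomas, or 31 in all, each from 1 tumour or skin. A further 10 papillomas without a risk label, on a second array design, entered no comparison. The labelled arrays held values for 16286 to 21494 of 21997 probes, and 2.29% to 26.0% of the probes on an array were empty. The number of arrays limits the precision. Values are log2 ratios of sample over reference, and this direction is likely rather than stated.

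Clustering by the pattern of empty probes, cut at 5 sets, placed the labelled arrays in sets A to E that did not follow the groups alone. The number of 5 was fixed by choice. In this pattern arrays correlated at 0.131 to 0.708 within sets and at -0.0966 to 0.284 between sets, so the sets were not sharply bounded. Set A held 4 normal skins and 1 high-risk papilloma. Set B held the 7 arrays of 6 low-risk papillomas, and set E held 4 high-risk papillomas. Set C held 4 high-risk papillomas, 2 carcinomas and 1 normal skin. Set D held 3 low-risk papillomas, 1 high-risk papilloma, 4 carcinomas and 1 normal skin. The spread of the ratios differed between sets, with a median SD of the arrays of 1 in A, 1.57 in B, 0.7 in C, 1.04 in D and 1.59 in E. Over the 5583 genes measured in every sample, the array set took up a median of 22.1% of the variance (adjusted R squared) and the group 7.58%. Set and group were fitted separately and partly coincide, so these shares overlap and that of the set can include group differences. Normal skin 1 and carcinoma 6, both in set C, differed by a median of 0.06 on the log2 scale over 16718 probes. This compares with 0.18 for the next closest pair of arrays. They correlated at r = 0.984 across probes, which are not independent replicates. The counts of called genes and the score were therefore also made without the pair.

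The comparison of high-risk with low-risk papillomas asked which genes separate benign tumours by their risk label. In high-risk papillomas Hbb-b2, a beta-globin chain, rose 7.66-fold, from a log2 level of -4.61 ± 1.40 (SD, n = 9) to -1.68 ± 1.49 (SD, n = 10). Vhl, which marks hypoxia-inducible factors for breakdown, rose 2.92-fold, and Egln3, an oxygen-dependent hydroxylase of the same factors, fell 2.72-fold. Cd2, an adhesion receptor of T cells, fell 3.19-fold and Lag3, an inhibitory receptor of the same cells, 2.92-fold, while the T-cell list did not pass. Limma called 126 of 18904 genes at an adjusted p under 0.05, 67 higher and 59 lower. The p-values rest on the spread within all 4 groups of the fit, normal skins and carcinomas included, moderated across genes. By their labels 6 high-risk tumours and 2 low-risk ones share a code with another, and the fit treated all tumours as separate.

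As log2 change ± SE with limma's adjusted p, the values of these genes were Hbb-b2 (2.94 ± 0.58, adjusted p = 0.0157), Vhl (1.54 ± 0.26, adjusted p = 0.00858), Egln3 (-1.44 ± 0.34, adjusted p = 0.038), Cd2 (-1.67 ± 0.40, adjusted p = 0.04) and Lag3 (-1.55 ± 0.37, adjusted p = 0.0437). The other large rises were in Elapor1 (2.09 ± 0.41, adjusted p = 0.0157), Tbpl1 (2.0 ± 0.49, adjusted p = 0.0485), Snord88c (1.59 ± 0.37, adjusted p = 0.0354), H2al1m (1.47 ± 0.28, adjusted p = 0.0126) and Ttll11 (1.43 ± 0.32, adjusted p = 0.0285). Ndn, an imprinted growth suppressor, rose (1.33 ± 0.31, adjusted p = 0.0359), as did Mdfic (1.24 ± 0.26, adjusted p = 0.023) and Btrc, which selects proteins for ubiquitin-dependent breakdown (1.23 ± 0.23, adjusted p = 0.0123). The largest falls were in Nek4, a kinase (-2.84 ± 0.51, adjusted p = 0.0108), Traf2, an adaptor of tumour necrosis factor receptors (-2.22 ± 0.44, adjusted p = 0.0157), and Uck2, an enzyme of pyrimidine salvage (-2.10 ± 0.40, adjusted p = 0.0123). Hamp, the iron hormone hepcidin, fell (-2.07 ± 0.51, adjusted p = 0.0459), and so did Lgals2 (-2.0 ± 0.40, adjusted p = 0.0157), Calcoco1 (-2.0 ± 0.40, adjusted p = 0.016) and Armc9 (-1.33 ± 0.30, adjusted p = 0.0285). All 20 were measured in the 10 high-risk and 9 low-risk tumours, and 9 or 10 of the 10 high-risk values lay on the stated side of the low-risk mean.

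None of 30 gene lists fixed in advance passed camera, limma's test of a list against the other genes, in this comparison. The smallest adjusted p was 0.0613, for terminal differentiation and the cornified envelope, where 0 of 27 members passed over all genes and 3 were lower when adjusted over the list alone. Its median log2 change was -0.54. Its smallest p-values were those of Tgm1 (-1.58 ± 0.41, adjusted p = 0.0565), a crosslinking enzyme of the envelope, Asprv1 (-1.67 ± 0.48, adjusted p = 0.0879) and Lce1a1 (-1.68 ± 0.49, adjusted p = 0.0881). Keratins and peptides of activated epidermis had a median of -0.42 (24 tested, 0 past the test, adjusted p = 0.12). Lcn2 (-2.34 ± 0.77, adjusted p = 0.121), Il1f6 (-1.34 ± 0.47, adjusted p = 0.145, n = 9 and 9) and Sprr3 (-1.94 ± 0.71, adjusted p = 0.161) led this list. On it high-risk papillomas of set C had means of 1.06 to 1.41, those of other sets 2.69 to 3.75 and low-risk papillomas 2.11 to 4.45. On terminal differentiation these means were 0.525 to 1.35, 2.08 to 2.88 and 1.91 to 3.33. High-risk papillomas outside set C thus lay within the low-risk range on both lists. Whether the narrow spread of set C lowered its values was not tested. As a block in the fit, the array set left terminal differentiation at a median of -0.24 (adjusted p = 0.433) and ribosomal proteins at -0.04 (0.61). Here and below, list p-values with the block or after scale normalization are of camera at the preset correlation. An estimated correlation was not tried there, so passing with the block does not show that a list would pass with one. Under this block the activated epidermis list passed (median -0.46, adjusted p = 0.0218). Within set D its median was 0.16 and that of terminal differentiation 0.18. After scale normalization between arrays the ribosomal protein list passed (adjusted p = 1.14e-07, median 0.48), against a median of 0.27 and an adjusted p of 0.0792 before.

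The difference between the risk groups was not separable from the array sets. With the array set as a block, limma called 0 genes, with 308 at an unadjusted p under 0.05. Within set D, the one set with both groups (1 against 3 tumours), it called 0 with 245, the lone tumour being assumed to vary like the others. A fit of the other sets alone (9 against 6 tumours) called 666 genes, of which 664 were measured in set D and 191 (28.8%) had the same direction there. The values of set D rest on high-risk papilloma 5, the only one of its group in set D, and partly on low-risk papilloma 6. On a score of genes chosen without the tumour scored, both lay with the other risk group (-2.23 and -0.182), so set D does not tell a set difference from wrong labels. With the set as a block Ttll11 (-0.01), Snord88c (-0.09), Tbpl1 (-0.12), Btrc (-0.04) and Egln3 (0.31) turned sign. The count was 0, with 2180 at an unadjusted p under 0.05, when only the 2 papilloma groups entered the fit, 37 after scale normalization and 1250 with array weights. It was 718 without high-risk papilloma 5 and 560 without low-risk papilloma 6.

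Carcinomas were compared with low-risk papillomas to find what separates malignant from low-risk benign tumours. Genes of keratinocyte terminal differentiation and the cornified envelope, the outer layer that keratinocytes build as they die, were lower in carcinomas as a list. The median log2 change of the 27 members was -1.34 (camera adjusted p = 6.17e-13, and adjusted p = 0.0331 with an estimated correlation between the genes). Among them 3 fell, 0 rose and 24 did not pass over all genes, and 17 were lower when adjusted over the list alone. Those that fell were Dsc1, a desmosomal cadherin (-2.22 ± 0.50, adjusted p = 0.0322, n = 4 and 9), Spink5, an inhibitor of skin proteases (-2.91 ± 0.71, adjusted p = 0.0389, n = 5 and 9), and Klk7, a protease that loosens the horny layer (-2.82 ± 0.71, adjusted p = 0.0433). The block by array set gave the list a median of -1.34 (camera adjusted p = 3.46e-08, at the preset correlation only) and within set D it was -1.37.

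Keratins and peptides of activated epidermis were lower in carcinomas too, with 4 of 24 members fallen, 0 risen and 6 lower when adjusted over the list alone. The median was -0.999 (camera adjusted p = 6.7e-08, and adjusted p = 0.161 with an estimated correlation). The 4 that fell were the beta-defensin Defb3 (-3.69 ± 0.93, adjusted p = 0.0443), the protease inhibitor Serpinb3a (-3.29 ± 0.75, adjusted p = 0.0265), the interleukin-1 family member Il1f6 (-2.46 ± 0.52, adjusted p = 0.0184) and Sprr2b (-2.09 ± 0.43, adjusted p = 0.0202, n = 4 and 9), a cornified envelope precursor. The median of this list was 0.03 after quantile normalization, -0.75 with the array set as a block (adjusted p = 5.1e-05) and -0.94 within set D.

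Limma called 212 genes between carcinomas and low-risk papillomas, 67 higher and 145 lower. Among the largest rises were Hbb-b2 (2.77 ± 0.67, adjusted p = 0.0344), Plac8 (2.50 ± 0.52, adjusted p = 0.0149), the lysozyme Lyz1 (2.13 ± 0.47, adjusted p = 0.0211), the interferon-induced GTPase Igtp (1.84 ± 0.47, adjusted p = 0.0461) and the galectin Lgals1 (1.53 ± 0.35, adjusted p = 0.0265). The others were Saraf (2.32 ± 0.49, adjusted p = 0.0184), a regulator of calcium entry, Osr2 (1.92 ± 0.38, adjusted p = 0.0105), Ugt2b37 (1.82 ± 0.37, adjusted p = 0.0131), Mup2 (1.81 ± 0.43, adjusted p = 0.0328) and Ttll11 (1.60 ± 0.37, adjusted p = 0.0282). Further large falls were in Sppl2b (-3.57 ± 0.83, adjusted p = 0.0282), Traf2 (-3.16 ± 0.50, adjusted p = 0.00247), the aldehyde oxidase Aox4 (-3.03 ± 0.70, adjusted p = 0.0282), Rbm12 (-2.99 ± 0.61, adjusted p = 0.0132) and the late cornified envelope gene Lce1i (-2.83 ± 0.70, adjusted p = 0.0395). The last were Lmod2 (-2.73 ± 0.38, adjusted p = 0.000349) and Nek4 (-2.71 ± 0.59, adjusted p = 0.0202), and all 6 carcinomas lay on the stated side of the low-risk mean for each of the 20.

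Of the other lists, 7 passed camera between carcinomas and low-risk papillomas, each with 0 members past the test over all genes and an adjusted p of 0.161 or more with an estimated correlation. Macrophages and monocytes were higher (median 0.56, adjusted p = 0.00937, and adjusted p = 0.161 with an estimated correlation, 1 of 24 higher over the list alone). The lysozyme gene Lyz2 (2.93 ± 0.79, adjusted p = 0.0578, n = 6 and 8) led it. Extracellular matrix was higher (median 0.38, adjusted p = 0.00937, and adjusted p = 0.601 with an estimated correlation, 28 tested). It was led by Col6a3 (0.87 ± 0.35, adjusted p = 0.204), a collagen whose probes disagreed, since their mean gave -0.09. Keratins of simple and internal epithelia were higher (median 0.74, adjusted p = 0.0303, and adjusted p = 0.161 with an estimated correlation, 3 of 11 over the list alone). Krt7 (1.67 ± 0.48, adjusted p = 0.0701, n = 6 and 8) and Krt19 (2.32 ± 0.71, adjusted p = 0.0999, n = 4 and 7) led these keratins. The mesenchymal transition list was higher (median 0.43, adjusted p = 0.042, and adjusted p = 0.367 with an estimated correlation, 16 tested). Its first gene was smooth muscle actin Acta2 (1.66 ± 0.56, adjusted p = 0.125). The cell cycle list was lower (median -0.23, adjusted p = 0.0129, and adjusted p = 0.22 with an estimated correlation, 3 of 40 over the list alone). Racgap1 (-1.20 ± 0.32, adjusted p = 0.0548, n = 5 and 9) led it with the replication helicase part Mcm4 (-2.22 ± 0.59, adjusted p = 0.0578, n = 6 and 8). Hair follicle genes were lower (median -0.51, adjusted p = 0.0303, and adjusted p = 0.601 with an estimated correlation, 16 tested). Krt86 (-1.64 ± 0.53, adjusted p = 0.113, n = 6 and 8) led them. Ribosomal proteins were lower (median -0.28, adjusted p = 0.000671, and adjusted p = 0.698 with an estimated correlation, 4 of 57 over the list alone). Rpsa (-1.08 ± 0.31, adjusted p = 0.0688) led them, but their median was 0.28 after quantile and 0.22 after scale normalization.

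Limma called 1 gene between carcinomas and low-risk papillomas with the array set as a block, with 1404 at an unadjusted p under 0.05. Within set D (4 carcinomas against 3 papillomas) it called 12. Of 22 genes called from the other sets alone (2 against 6) 17 had the same direction in set D (77.3%), a share that 3 of the 35 splits of set D reached (p = 0.0857). With the block extracellular matrix (median 0.47, adjusted p = 0.000971), the cell cycle (-0.11, 0.0114) and ribosomal proteins (-0.21, 0.0123) passed. The other 4 lists had adjusted p-values of 0.122 to 0.146. Within set D the medians were 0.65, -0.18 and -0.28 for these 3, 0.36 for macrophages, 0.41 for simple epithelia, 0.30 for the mesenchymal list and -0.45 for hair follicle. With the block they were 0.29, 0.39, 0.29 and -0.27 for these 4. The count was 739 without low-risk papilloma 6 and 51 without carcinoma 3.

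Between carcinomas and high-risk papillomas only 8 genes passed, 4 higher and 4 lower in carcinomas. Gsr, the enzyme that restores glutathione, was 3.14-fold higher, in 6 of 6 carcinomas (1.65 ± 0.33, adjusted p = 0.0498). The other 7 were chosen for naming after their values were seen, because so few passed. Higher were Plet1 (2.51 ± 0.46, adjusted p = 0.0288, n = 5 and 9), Saraf (2.93 ± 0.49, adjusted p = 0.0143, n = 6 and 9) and the platelet chemokine Ppbp (2.02 ± 0.31, adjusted p = 0.0143, n = 4 and 6). Lower were Lce1e (-3.73 ± 0.61, adjusted p = 0.0143, n = 4 and 6), Irak1, a kinase of interleukin-1 signalling (-1.65 ± 0.33, adjusted p = 0.0498, n = 6 and 9), Ltb4r1, a leukotriene receptor (-3.86 ± 0.68, adjusted p = 0.0288, n = 4 and 6), and 1 unnamed probe. Of the 8, only 4 could be compared within set C, and those with n = 4 and 6 could not.

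As lists, 12 passed camera between carcinomas and high-risk papillomas with 0 members past the test over all genes, and each had an adjusted p of 0.213 or more with an estimated correlation. Ribosomal proteins were lower in carcinomas (median -0.50, adjusted p = 2.1e-12, and adjusted p = 0.235 with an estimated correlation), led by Rps3a1 (-1.18 ± 0.34, adjusted p = 0.209). Terminal differentiation was lower (-0.92, 2.18e-07, and adjusted p = 0.213 with an estimated correlation). The suprabasal keratin Krt10 (-1.50 ± 0.35, adjusted p = 0.117) and the lipoxygenase Aloxe3 (-1.98 ± 0.58, adjusted p = 0.207) led it. Activated epidermis (-0.73, 0.000212, and adjusted p = 0.235 with an estimated correlation) was lower with Sprr2b (-1.94 ± 0.47, adjusted p = 0.133, n = 4 and 6) and S100a9 (-1.84 ± 0.55, adjusted p = 0.224, n = 4 and 6), a calcium-binding alarmin. The cell cycle (-0.26, 0.0139, and adjusted p = 0.235 with an estimated correlation) was lower with Racgap1 (-1.40 ± 0.32, adjusted p = 0.116, n = 5 and 9) and Cenpa (-1.29 ± 0.30, adjusted p = 0.117). Oxidative phosphorylation (-0.20, 0.0124, and adjusted p = 0.534 with an estimated correlation) was lower with Cox7a2 (-0.79 ± 0.26, adjusted p = 0.28). Basal keratinocytes (-0.61, 0.0297, and adjusted p = 0.235 with an estimated correlation) were lower with Col17a1 (-2.30 ± 0.85, adjusted p = 0.333, n = 6 and 9). Adjusted over the list alone, 4 of 27 members of terminal differentiation, 2 of 24 of activated epidermis and 3 of 40 of the cell cycle were lower.

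Extracellular matrix was higher in carcinomas than in high-risk papillomas (median 0.48, adjusted p = 9.85e-05, and adjusted p = 0.235 with an estimated correlation). The matrix proteins Postn (1.47 ± 0.46, adjusted p = 0.233, n = 6 and 8) and Tnc (1.33 ± 0.44, adjusted p = 0.28) led it. Macrophages and monocytes were higher (0.55, 0.00398, and adjusted p = 0.213 with an estimated correlation), with Tyrobp (1.15 ± 0.34, adjusted p = 0.22, n = 5 and 8) and the scavenger receptor Msr1 (1.05 ± 0.36, adjusted p = 0.289). Fibroblasts (0.51, 0.0139), simple epithelia (0.92, 0.0297), the mesenchymal list (0.47, 0.0297) and adipocytes (0.42, 0.0297) were higher. They had an adjusted p of 0.235, 0.213, 0.235 and 0.235 with an estimated correlation. Their leading members were Sfrp2 (0.65 ± 0.26, adjusted p = 0.38), Krt4 (1.23 ± 0.45, adjusted p = 0.331), Zeb2 (0.70 ± 0.31, adjusted p = 0.423) and the adipokine Adipoq (2.60 ± 0.82, adjusted p = 0.261, n = 4 and 6). The block by array set left 0 genes past limma, with 451 at an unadjusted p under 0.05. Of the lists that had passed, only terminal differentiation (median -0.70, adjusted p = 3e-07), extracellular matrix (0.32, 0.000544) and ribosomal proteins (-0.15, 0.00315) passed. Within set C (2 against 4) limma called 2 genes and the medians of these 3 lists were -0.01, -0.14 and 0.11. Within set D (4 against high-risk papilloma 5, with the same assumption as above) it called 1 gene and they were -1.37, 0.77 and -0.26. Of genes called from the other sets alone, 115 of 232 (49.6%) had the same direction in set C and 0 of 2 in set D.

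The other 9 lists that passed between carcinomas and high-risk papillomas did not pass with the array set as a block (adjusted p-values of 0.0678 to 0.986). With the block, in set C and in set D the medians were -0.36, 0.67 and -1.20 for activated epidermis, 0.26, 0.13 and 0.52 for macrophages and -0.04, -0.11 and 0.16 for oxidative phosphorylation. They were -0.09, -0.03 and -0.16 for the cell cycle. The medians for fibroblasts were -0.07, -0.12 and 0.01, and for adipocytes 0.18, 0.17 and -0.13. The rest were 0.20, -0.01 and 0.76 for simple epithelia, 0.05, -0.17 and 0.17 for the mesenchymal list and -0.28, -0.22 and -0.26 for basal keratinocytes. The count of 8 fell to 0 without high-risk papilloma 2, carcinoma 2 or carcinoma 3, with 1561, 1386 and 1457 genes at an unadjusted p under 0.05, and was 95 after quantile normalization.

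Low-risk papillomas were compared with normal skin to find what the benign tumours had gained or lost. Activated epidermis had the largest median among the lists that passed, with 14 of 24 members risen, 0 fallen and 17 higher when adjusted over the list alone. The median was 2.28 (camera adjusted p = 6.15e-16, and adjusted p = 0.0419 with an estimated correlation). S100a9 and S100a8, which form the alarmin calprotectin, rose 49.1-fold and 22.1-fold (5.62 ± 0.47, adjusted p = 1.34e-07, n = 9 and 5 and 4.47 ± 0.71, adjusted p = 0.000332). S100a8 was measured in every normal skin, normal skin 1 included, and S100a9 was not, so these folds are not on like samples. Il1b, the inflammatory cytokine interleukin-1 beta, rose 14.3-fold (3.84 ± 0.63, adjusted p = 0.000593), and the envelope precursor Sprr2i (2.30 ± 0.36, adjusted p = 0.000275) rose with them. As a block the array set gave this list a median of 1.58 (adjusted p = 6.58e-11) and within set D it was 1.60.

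The other 5 lists that passed camera in low-risk papillomas did not pass with an estimated correlation. Terminal differentiation had 4 of 27 members risen (4 over the list alone, median 0.61, adjusted p = 0.00205, and adjusted p = 0.486 with an estimated correlation). Lce1m (2.13 ± 0.52, adjusted p = 0.0109) and Spink5 (2.72 ± 0.71, adjusted p = 0.0184, n = 9 and 5) were among them. Ribosomal proteins had 7 of 57 risen (14 over the list alone, median 0.47, adjusted p = 5.26e-07, and adjusted p = 0.486 with an estimated correlation). Rpl41 (1.20 ± 0.21, adjusted p = 0.000803) was among them. The cell cycle had 4 of 40 risen and 1 fallen (the same numbers over the list alone, median 0.41, adjusted p = 0.00327, and adjusted p = 0.162 with an estimated correlation). Birc5, the survivin gene (1.42 ± 0.22, adjusted p = 0.000301), and Mcm7 (0.98 ± 0.20, adjusted p = 0.00357) led it. Oxidative phosphorylation had 4 of 48 risen (4 over the list alone, median 0.22, adjusted p = 0.0439, and adjusted p = 0.529 with an estimated correlation). Ndufa4 (1.79 ± 0.36, adjusted p = 0.00268) led it. Dendritic cells and MHC class II had 2 of 14 fallen (2 over the list alone, median -0.32, adjusted p = 0.0307, and adjusted p = 0.151 with an estimated correlation). The pair were Ciita, the class II transactivator (-0.92 ± 0.21, adjusted p = 0.0057), and H2-DMb1 (-0.98 ± 0.30, adjusted p = 0.0445).

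Limma called 1427 genes between low-risk papillomas and normal skin, 744 higher and 683 lower. Without centring of the arrays they were 651 and 753, so the larger side depended on the scaling. Besides those named, the largest rises were in Olfr29-ps1 (4.02 ± 0.67, adjusted p = 0.000669), Nek4 (3.71 ± 0.59, adjusted p = 0.000335), the monooxygenase Fmo5 (3.54 ± 0.70, adjusted p = 0.00228) and Rhoh (3.47 ± 0.56, adjusted p = 0.000571), a GTPase of blood cells. The largest falls were in Rtkn2 (-3.85 ± 0.35, adjusted p = 4.42e-08), Boll (-3.32 ± 0.81, adjusted p = 0.0117), Mup2 (-3.20 ± 0.43, adjusted p = 5.98e-05), Chac2 (-3.05 ± 0.40, adjusted p = 4.4e-05), Hsd11b2 (-2.95 ± 0.71, adjusted p = 0.0103), which inactivates glucocorticoids, and Taf12 (-2.74 ± 0.47, adjusted p = 0.000737). For the 12 genes with the largest changes 8 or 9 of the 9 papillomas lay on the stated side of the normal mean. Further risen genes were the glutathione transferase Gsta1 (2.28 ± 0.58, adjusted p = 0.016), thioredoxin Txn1 (1.94 ± 0.48, adjusted p = 0.0144, n = 9 and 5) and the BMP target Id1 (1.54 ± 0.28, adjusted p = 0.00116). Of macrophage genes Arg1 (3.13 ± 0.60, adjusted p = 0.002) rose and Apoe (-1.99 ± 0.46, adjusted p = 0.00721) fell, of the hypoxia and glycolysis list Pgam1 (1.60 ± 0.31, adjusted p = 0.00212) rose and P4ha2 (-0.97 ± 0.23, adjusted p = 0.00891, n = 8 and 5) fell, and of neutrophil genes Il1b rose and Fpr2 (-1.52 ± 0.47, adjusted p = 0.0452) fell. The mast cell genes Cpa3 (0.68 ± 0.19, adjusted p = 0.0294, n = 9 and 5) and Fcer1a (1.33 ± 0.39, adjusted p = 0.0354, n = 8 and 6) rose, while of T-cell genes Cd2 rose (3.28 ± 0.45, adjusted p = 7.6e-05) and Cd3e (-1.04 ± 0.23, adjusted p = 0.00489) and Cd8a (-1.21 ± 0.28, adjusted p = 0.00847) fell. Hair keratins Krt33a (-1.85 ± 0.39, adjusted p = 0.00417) and Krt71 (-2.08 ± 0.47, adjusted p = 0.00832, n = 9 and 4) and skeletal actin Acta1 (-4.24 ± 0.88, adjusted p = 0.00404, n = 9 and 5) fell and the muscle gene Ttn (0.99 ± 0.28, adjusted p = 0.0251) rose, though the mean over its probes gave 0.05. None of their lists passed.

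Normal skin 1, the array that resembled carcinoma 6, took part in these values. Without the pair limma called 1526 genes, of which 1270 were among the 1427. Limma called 5 with the array set as a block, with 1252 at an unadjusted p under 0.05. Within set D (3 papillomas against 1 skin, whose spread was taken from the other samples) it called 9. Of 1046 genes called from the other sets alone and measured in set D, 851 (81.4%) had the same direction there, though 4 splits allow no p below 0.25. The log2 changes of named genes that moved most without the pair became 3.83 for Arg1, 2.93 for Gsta1, 5.09 for S100a8, 4.53 for Olfr29-ps1, -3.47 for Taf12, -3.61 for Chac2, -2.51 for Apoe and -4.36 for Rtkn2. The block left activated epidermis and ribosomal proteins past the test. The latter had a median of 0.37 (adjusted p = 3.77e-05), and 0.07 within set D. The block ended the other calls with adjusted p-values of 0.0647 to 0.644. Their medians within set D were 0.19 for terminal differentiation, 0.16 for the cell cycle, 0.15 for oxidative phosphorylation and -0.51 for MHC class II. With the block they were 0.26, 0.19, 0.15 and -0.33.

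High-risk papillomas were compared with normal skin to ask the same of them. Of activated epidermis 8 of 24 members rose, 0 fell and 13 were higher when adjusted over the list alone. The median was 1.46 (camera adjusted p = 7.73e-12, and adjusted p = 0.161 with an estimated correlation). S100a9 rose 72.8-fold (6.18 ± 0.51, adjusted p = 2e-07, n = 6 and 5), S100a8 16.3-fold (4.03 ± 0.69, adjusted p = 0.00109) and the protease inhibitor Stfa1 11.5-fold (3.52 ± 0.71, adjusted p = 0.00408). The n of S100a9 equal the numbers of samples outside set C. S100a8 was measured in every sample, normal skin 1 included, so the folds of S100a9 and S100a8 are not on like samples. Hair follicle genes fell in 4 of 16 cases (6 over the list alone, median -0.60, adjusted p = 0.0135, and adjusted p = 0.305 with an estimated correlation). The hair keratin Krt34 was 9.47-fold lower (-3.24 ± 0.48, adjusted p = 0.000208), and Krt71 (-2.37 ± 0.49, adjusted p = 0.00693, n = 7 and 4) fell. Over the probes measured in every sample only 3 hair follicle genes were left, with a median of 0.56.

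Ribosomal proteins rose in 8 of 57 cases in high-risk papillomas (28 over the list alone, median 0.76, adjusted p = 1.09e-14, and adjusted p = 0.244 with an estimated correlation), led by Rpl41 (0.97 ± 0.21, adjusted p = 0.00601). Oxidative phosphorylation rose in 8 of 48 (12 over the list alone, median 0.39, adjusted p = 2.45e-05, and adjusted p = 0.267 with an estimated correlation), led by Cox7a2 (1.28 ± 0.26, adjusted p = 0.0048). The NRF2 and glutathione list rose in 4 of 23 (7 over the list alone, median 0.59, adjusted p = 0.000243, and adjusted p = 0.244 with an estimated correlation). Txn1 (2.72 ± 0.52, adjusted p = 0.00394, n = 6 and 5) and the peroxiredoxin Prdx1 (1.18 ± 0.29, adjusted p = 0.0168) led it. The cell cycle rose in 2 of 40 (5 over the list alone, median 0.31, adjusted p = 0.00354, and adjusted p = 0.244 with an estimated correlation). They were Birc5 (1.15 ± 0.22, adjusted p = 0.00258) and Kif11 (1.07 ± 0.28, adjusted p = 0.0229). EGFR ligands and the Ras-MAPK response rose in 2 of 28 (3 over the list alone, median 0.41, adjusted p = 0.0415, and adjusted p = 0.267 with an estimated correlation). These were the EGFR ligand Tgfa (1.19 ± 0.32, adjusted p = 0.0256) and Spred2 (0.80 ± 0.22, adjusted p = 0.0337), an inhibitor of the pathway. Adipocyte genes fell in 1 of 13 (3 over the list alone, median -0.79, adjusted p = 0.0121, and adjusted p = 0.244 with an estimated correlation). Leptin, Lep (-0.90 ± 0.20, adjusted p = 0.0075, n = 8 and 6), was the one.

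Limma called 948 genes between high-risk papillomas and normal skin, 486 higher and 462 lower. The other largest rises were plasminogen Plg (3.80 ± 1.10, adjusted p = 0.0385), Hbb-b2 (3.51 ± 0.66, adjusted p = 0.00235), Rps6kb2 (2.50 ± 0.56, adjusted p = 0.0093) and Lce3c (2.44 ± 0.68, adjusted p = 0.0313). The size of the rise of Plg rests in part on high-risk papilloma 2, at 12.7 where the others ran from 2.54 to 7.17. The other largest falls were Chac2 (-3.33 ± 0.39, adjusted p = 6.73e-06), Taf12 (-3.21 ± 0.46, adjusted p = 0.000156), Rtkn2 (-3.05 ± 0.34, adjusted p = 2.35e-06), Sypl2 (-2.84 ± 0.82, adjusted p = 0.0386) and Zfp821 (-2.83 ± 0.67, adjusted p = 0.0121). That of Sypl2 rests in part on high-risk papilloma 1, at -8.24 where the others ran from -1.94 to 0.584. All 10 papillomas lay on the stated side of the normal mean for the 12 genes with the largest changes. Some lists that did not pass held called genes of both directions. Of neutrophil genes Ppbp (1.54 ± 0.30, adjusted p = 0.00408, n = 6 and 5), Il1b (2.97 ± 0.63, adjusted p = 0.00683, n = 9 and 6) and Cxcl1 (1.25 ± 0.37, adjusted p = 0.042) rose and Fpr2 (-2.03 ± 0.47, adjusted p = 0.0118, n = 9 and 6) fell. Of macrophage genes Arg1 (2.92 ± 0.60, adjusted p = 0.00511, n = 9 and 6), Ccl2 (1.86 ± 0.50, adjusted p = 0.0289, n = 8 and 6) and Ccl3 (1.56 ± 0.43, adjusted p = 0.0313, n = 9 and 6) rose and Tyrobp (-1.22 ± 0.34, adjusted p = 0.0349, n = 8 and 5) fell. Of the hypoxia and glycolysis list Pgam1 (1.27 ± 0.31, adjusted p = 0.0138) rose and Pkm (-1.66 ± 0.40, adjusted p = 0.015) fell, and of the TGF-beta and BMP list Id1 (1.25 ± 0.28, adjusted p = 0.00778) rose and Ccn2 (-1.28 ± 0.32, adjusted p = 0.0188) fell. Of muscle genes Tnnc2 (-2.23 ± 0.53, adjusted p = 0.0167, n = 8 and 6) and Acta1 (-3.30 ± 0.88, adjusted p = 0.0273, n = 9 and 5) fell and Ttn (1.14 ± 0.27, adjusted p = 0.0129) rose, though the mean over the probes of Ttn gave -0.11.

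Without the pair limma called 1363 genes between high-risk papillomas and normal skin, 917 of them among the 948. The block by array set left 12, with 2188 at an unadjusted p under 0.05. Within sets limma called 499 in A (1 papilloma against 4 skins), 0 in C (4 against 1, with 199 at an unadjusted p under 0.05) and 2 in D (high-risk papilloma 5 against 1 skin). Each set had a single sample on 1 side, whose spread was taken from the other samples, so these counts do not test the comparison within sets. Of genes called from the other sets alone, 3 of 3 had the same direction in A, 792 of 1637 (48.4%) in C, whose normal skin is normal skin 1, and 317 of 440 (72%) in D. The log2 changes of named genes that moved most without the pair became 4.64 for Plg, 3.62 for Arg1, 3.14 for Lce3c, 4.65 for S100a8, -3.94 for Taf12, -3.81 for Krt34, -3.89 for Chac2 and -3.56 for Rtkn2. Activated epidermis (median 0.70, adjusted p = 1.31e-05), hair follicle (-0.47, 0.00397), adipocytes (-0.64, 0.00224) and ribosomal proteins (0.34, 2.48e-05) passed with the block. The other 4 lists did not (adjusted p-values of 0.279 to 0.607). In sets A, C and D the medians were 1.90, -0.60 and 1.40 for activated epidermis and -0.57, 0.01 and -1.53 for hair follicle. They were -1.01, -0.43 and -0.20 for adipocytes and 1.00, 0.00 and 0.13 for ribosomal proteins, and the only normal skin of set C was normal skin 1. For oxidative phosphorylation they were 0.20, 0.12 and -0.07 (0.18 with the block) and for NRF2 0.56, -0.22 and 0.32 (0.19). The values were, for the cell cycle, 0.23, 0.02 and 0.18 (0.04), and for the EGFR list 0.58, -0.12 and 0.24 (0.27). The count was 362 without normal skin 6 and 1794 after quantile normalization.

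Carcinomas were compared with normal skin to find what separates the malignant tumours from it. S100a9 rose 20.3-fold (4.35 ± 0.57, adjusted p = 0.000158, n = 4 and 5), the chemokine Ppbp 11.9-fold (3.57 ± 0.33, adjusted p = 1.55e-06, n = 4 and 5) and arginase Arg1 7.58-fold (2.92 ± 0.66, adjusted p = 0.0215). Lactate dehydrogenase A, Ldha, the last step of anaerobic glycolysis, rose 3.71-fold (1.89 ± 0.36, adjusted p = 0.00609), with Pgam1 (1.49 ± 0.34, adjusted p = 0.0235). Krt15, a keratin of basal and hair follicle stem cells, fell 8.01-fold (-3.0 ± 0.65, adjusted p = 0.0151), and the hair keratins Krt34 (-2.52 ± 0.53, adjusted p = 0.0129) and Krt33a (-2.02 ± 0.43, adjusted p = 0.0136) fell.

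Limma called 219 genes between carcinomas and normal skin, 48 higher and 171 lower, and all 6 carcinomas lay on the stated side of the normal mean for the 12 genes with the largest changes. The other large rises were Hbb-b2 (3.34 ± 0.73, adjusted p = 0.0167), Pibf1 (2.27 ± 0.59, adjusted p = 0.0484), Ugt2b37 (2.11 ± 0.41, adjusted p = 0.00742) and the glutathione transferase Gsta2 (2.05 ± 0.53, adjusted p = 0.049). The other large falls were Taf12 (-3.33 ± 0.52, adjusted p = 0.000576), Chac2 (-3.22 ± 0.44, adjusted p = 0.000102), Rtkn2 (-2.77 ± 0.38, adjusted p = 0.000102), Prrg2 (-2.71 ± 0.38, adjusted p = 0.000109) and Phyhd1 (-2.70 ± 0.65, adjusted p = 0.0338). After quantile normalization the calls were 366 higher and 524 lower, after scale normalization 274 and 441.

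Of the lists, 13 passed camera between carcinomas and normal skin, each with an adjusted p of 0.0962 or more with an estimated correlation. Activated epidermis had 1 of 24 members risen (4 over the list alone, median 0.67, adjusted p = 3.14e-05, and adjusted p = 0.188 with an estimated correlation). Hair follicle had 3 of 16 fallen (6 over the list alone, median -0.45, adjusted p = 0.000129, and adjusted p = 0.174 with an estimated correlation), and the 3 genes measured in every sample had a median of 0.06. Terminal differentiation had 0 of 27 past the test (3 lower over the list alone, median -0.56, adjusted p = 0.00188, and adjusted p = 0.234 with an estimated correlation), with Krt2 (-1.34 ± 0.38, adjusted p = 0.0838). Extracellular matrix (median 0.51, adjusted p = 0.000129, and adjusted p = 0.188 with an estimated correlation) had 0 of 28 past the test and 2 over the list alone, with the collagen Col1a2 (2.12 ± 0.66, adjusted p = 0.117). Proteases (0.37, 0.00356, and adjusted p = 0.0962 with an estimated correlation) had 0 of 25 past the test and 0 over the list alone. Their leading genes were the matrix protease Mmp3 (1.36 ± 0.41, adjusted p = 0.106) and the urokinase receptor Plaur (0.78 ± 0.25, adjusted p = 0.138). NRF2 and glutathione had 2 of 23 risen (4 over the list alone, median 0.32, adjusted p = 0.000612, and adjusted p = 0.188 with an estimated correlation), Gsta2 and Gsr (1.65 ± 0.37, adjusted p = 0.0196). Hypoxia and glycolysis had 2 of 19 (5 higher and 3 lower over the list alone, median 0.51, adjusted p = 0.00713, and adjusted p = 0.188 with an estimated correlation), Ldha and Pgam1.

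Macrophages and monocytes had 1 of 24 risen in carcinomas against normal skin, Arg1 (1 higher and 1 lower over the list alone, median 0.48, adjusted p = 0.00152, and adjusted p = 0.0962 with an estimated correlation). Neutrophils and their chemokines had 1 of 18, Ppbp (2 over the list alone, median 0.22, adjusted p = 0.0274, and adjusted p = 0.188 with an estimated correlation). Simple epithelia had 0 of 11 (1 over the list alone, median 0.50, adjusted p = 0.00579, and adjusted p = 0.0962 with an estimated correlation), with Krt4 (1.76 ± 0.51, adjusted p = 0.0864). Oxidative phosphorylation had 1 of 48 risen, Ndufa4 (1.54 ± 0.39, adjusted p = 0.0443) (2 over the list alone, median 0.24, adjusted p = 0.0182, and adjusted p = 0.511 with an estimated correlation). Ribosomal proteins had 0 of 57 (0 over the list alone, median 0.18, adjusted p = 0.0216, and adjusted p = 0.599 with an estimated correlation), with Rpl27a (1.01 ± 0.30, adjusted p = 0.0946). The EGFR and Ras-MAPK list had 0 of 28 (2 higher and 1 lower over the list alone, median 0.23, adjusted p = 0.024, and adjusted p = 0.203 with an estimated correlation). Spry1, an inhibitor of the pathway, did not pass (-1.08 ± 0.31, adjusted p = 0.0838). Over the probes measured in every sample the EGFR list had a median of -0.06 (8 genes), and the 1 neutrophil gene left had -0.46.

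Without normal skin 1 and carcinoma 6 limma called 488 genes between carcinomas and normal skin, which held all 219, and 549 without normal skin 1 alone. The block by set left 10, with 1206 at an unadjusted p under 0.05. Within sets it called 0 in C (2 carcinomas against normal skin 1, with 4 at an unadjusted p under 0.05) and 37 in D (4 against 1), the single skins being assumed to vary like the other samples. Of genes called from the other sets alone 188 of 378 (49.7%) had the same direction in C, and without D 0 genes were called. The log2 changes of named genes that moved most without the pair became 3.47 for Arg1, 4.05 for Hbb-b2, -4.0 for Taf12, -3.85 for Chac2, -3.6 for Krt15, -3.03 for Krt34, -3.25 for Phyhd1, -3.22 for Prrg2 and -3.32 for Rtkn2. With the block hair follicle (median -0.85, adjusted p = 6.76e-06), terminal differentiation (-0.67, 0.000344) and activated epidermis (0.60, 0.000344) were the lists with the smallest p. Extracellular matrix, neutrophils, hypoxia and glycolysis, the EGFR list and oxidative phosphorylation no longer passed (adjusted p-values of 0.0577 to 0.558). In sets C and D the medians were -0.14 and -1.98 for hair follicle, -0.44 and -0.95 for terminal differentiation, -0.18 and 0.75 for activated epidermis and -0.08 and 0.57 for extracellular matrix (0.20 with the block). They were -0.21 and 0.35 for NRF2 (0.23 with the block, adjusted p = 0.00304), -0.04 and 0.62 for macrophages (0.49, 0.0263) and -0.11 and 0.33 for proteases (0.21, 0.0358). Simple epithelia had -0.08 and 0.36 (0.45, 0.0358) and ribosomal proteins -0.06 and -0.19 (0.15, 0.0263). The medians were 0.01 and 0.30 for hypoxia and glycolysis (0.40 with the block), 0.06 and -0.07 for oxidative phosphorylation (0.14), -0.07 and 0.21 for the EGFR list (0.24) and -0.11 and 0.18 for neutrophils (0.20).

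**Figure D1:**
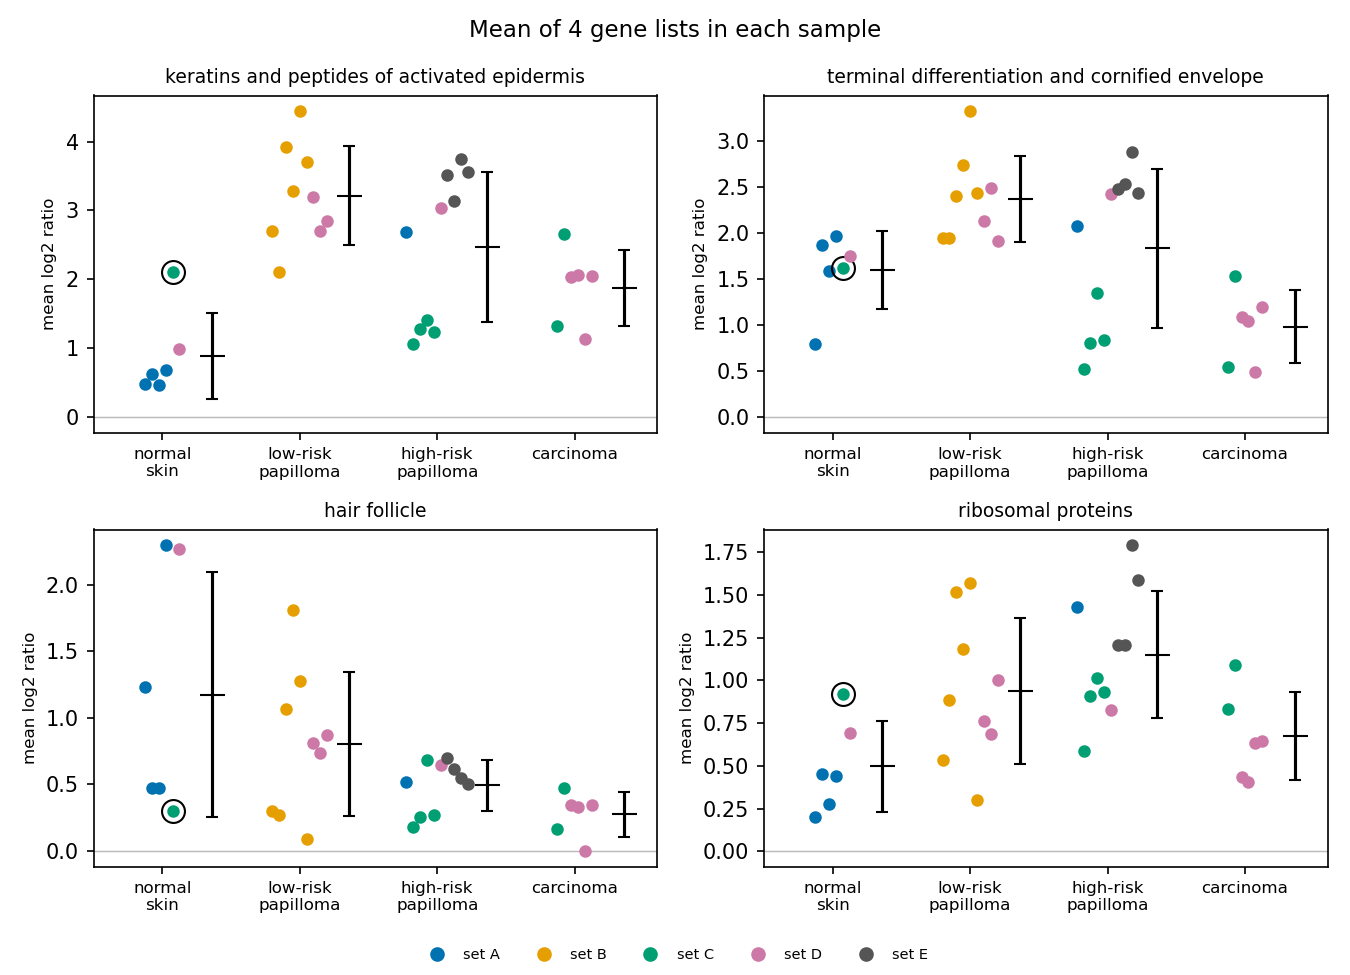
Mean log2 ratio of sample over reference of the genes of 4 lists (vertical axis) in each of the 31 samples, by group, with a bar at the group mean ± SD and the colour giving the array set. Normal skin 1, ringed, lies apart from the other normal skins in activated epidermis.

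A score placed each papilloma on the line from normal skin to carcinoma, to ask which papillomas lay nearer to carcinoma. It is the slope of a sample's log2 difference from normal skin on the mean difference of carcinomas from normal skin over 18904 genes. The mean of normal skins is thus near 0 and that of carcinomas near 1. High-risk papillomas scored 0.733 ± 0.0792 (SD, n = 10) and low-risk papillomas 0.706 ± 0.224 (SD, n = 9). The difference of 0.027 was smaller than the spread within either group (exact 2-sided permutation test over 92378 splits, p = 0.748). Within set D, the one set with both groups, it was -0.118 (1 against 3, exact permutation p = 0.75 over 4 splits, which allow no p below 0.25), and it rests on high-risk papilloma 5 and partly on low-risk papilloma 6, whose risk labels are in doubt. Over the 219 genes called between carcinomas and normal skin alone, the scores were 0.854 ± 0.0585 and 0.763 ± 0.0894, a difference of 0.0908 (exact permutation p = 0.0162). Within set D the difference over these genes was -0.0665 (exact permutation p = 0.75).

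**Figure D2:**
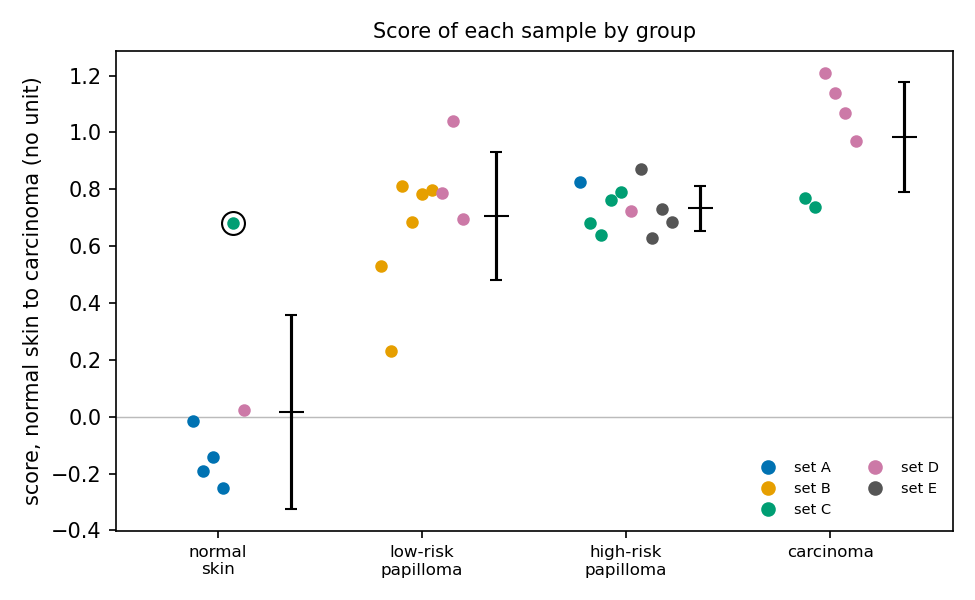
Score on the line from normal skin to carcinoma (vertical axis, no unit) of the 31 samples by group, with a bar at the group mean ± SD and the colour giving the array set. High-risk and low-risk papillomas overlap, and normal skin 1, ringed, scores 0.682 among the papillomas.

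The changes of high-risk papillomas and of carcinomas against low-risk papillomas went together across 18904 genes (r = 0.583, genes not being independent replicates), but both share the low-risk tumours. Simulated unchanged groups, which shared a low-risk group that was simulated too, gave a median r of 0.454 (0.429 to 0.482 over 100 draws). Splitting the real low-risk tumours between the comparisons gave a median of 0.205 (-0.0578 to 0.42 over 100 draws). The covariance was 0.216 against 0.0776 simulated, a difference of 0.138, and 0.0991 with split tumours. The simulation left out the array sets and the correlation between genes. Its narrow range therefore cannot show that the observed r lies beyond chance. Of the 9 low-risk papillomas 6 lay in set B, which held no high-risk papilloma or carcinoma, so a difference of that set would also give a shared change.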

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

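All tests of explanations in this part were chosen after the results were seen, and so were the array sets and the comparison without the pair. Values of each named gene and of the score were searched for a sample apart from the rest of its group, by the gap to its nearest neighbour divided by the range of the group, at the 95% limit of Dixon's test. Chance gives about 1 in 20 groups, or 27.2 of 544, and 57 were found. Of these, 25 were normal skin 1, and each value below is that share of the range.

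Normal skin 1 lay above the other normal skins in the score (0.706) and in Saraf (0.871), Defb3 (0.895), Gsr (0.741), S100a8 (0.766), Olfr29-ps1 (0.756), Rhoh (0.753), Ndufa4 (0.685), Gsta1 (0.788), Arg1 (0.645), Plg (0.747), Rps6kb2 (0.681), Lce3c (0.889), Tgfa (0.764), Gsta2 (0.699) and Ldha (0.876). It lay below them in Calcoco1 (0.626), Sprr3 (0.694), Rtkn2 (0.74), Chac2 (0.776), Taf12 (0.781), Sypl2 (0.66), Lep (0.679), Prrg2 (0.75) and Apoe (0.684). Of the other normal skins, number 3 was lowest in Rpsa (0.628) and highest in Lyz2 (0.641), and number 2 lowest in Snord88c (0.691).

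Among carcinomas, number 3 was highest in Lgals1 (0.629) and lowest in Dsc1 (0.884), S100a9 (0.863) and Il1b (0.751). Carcinoma 1 was lowest in Rtkn2 (0.7), Hsd11b2 (0.714) and Sypl2 (0.778) and highest in Fpr2 (0.667) and Pkm (0.66), carcinoma 2 highest in Sfrp2 (0.66) and Krt34 (0.665), and carcinoma 6 highest in Il1f6 (0.706). Among high-risk papillomas, number 5 was highest in Uck2 (0.601), Lgals2 (0.475) and Egln3 (0.512), which fell in its group. Number 1 was lowest in Sypl2 (0.715) and highest in Gsta2 (0.567), number 2 highest in Plg (0.544), number 3 lowest in Mcm7 (0.61) and Phyhd1 (0.609), number 8 lowest in Rhoh (0.572) and Chac2 (0.499), and number 10 highest in Cpa3 (0.605) and lowest in Fcer1a (0.814). Among low-risk papillomas, number 9 was lowest in Col17a1 (0.497) and Chac2 (0.607) and highest in Spry1 (0.535), number 2 lowest in Defb3 (0.68) and number 7 highest in P4ha2 (0.532).

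The first pattern weighed is that normal skin 1 and carcinoma 6 were near-identical, with a median difference over probes of 0.064 against 0.177 for the next closest pair of arrays, which is consistent with one RNA on both arrays. On a score made without the pair they had 0.732 and 0.748, where the other normal skins, each left out of the score in turn, ran from -0.0232 to 0.294. The high-risk papillomas of their set C differed from those of other sets by -0.0257, which argues against an upward shift of the set that is alike in all groups. They differed from normal skin 1 and carcinoma 6 by -0.00453 and -0.0198, where high-risk papillomas of sets A and D lay 0.72 and 0.431 above normal skin. Unless the set brought its groups to 1 level, these values argue against carcinoma 6 being normal skin. A wrong label of normal skin 1 may then be the explanation. Set C holds no other normal skin and its carcinoma 5 had 0.784, below the other sets (0.942 or more), so an effect that brings its groups to 1 level stays open, as does whether the RNA came from a carcinoma or a papilloma.

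The second pattern is that the difference between high-risk and low-risk papillomas followed the array sets. In set D, the one set with both groups, 28.8% of 664 genes called from the other sets had the same direction, but the value rests on high-risk papilloma 5, its only high-risk tumour, and partly on low-risk papilloma 6, whose labels the third pattern puts in doubt. Across genes, which are not independent replicates, the difference of high-risk papillomas of sets E and C correlated with the risk contrast at r = 0.213, that of low-risk papillomas of sets B and D at -0.278 and that of carcinomas of sets C and D at 0.237. The differences within papillomas share their tumours with the risk contrast, so part of these correlations may be shared noise, which was not estimated. With the set as a block 308 genes had an unadjusted p under 0.05, where chance gives 945, but only 1 high-risk papilloma shares a set with low-risk ones. A difference between the risk groups, a difference between array sets and wrong labels cannot be told apart, and all stay open.

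The third pattern is that high-risk papilloma 5 and low-risk papilloma 6 scored with the other risk group, on the mean difference of genes chosen without the tumour scored. High-risk papilloma 5 had -2.23 and low-risk papilloma 6 had -0.182. The other high-risk papillomas ran from -1.37 to 0.142 and the other low-risk ones from -3.11 to -1.87, so swapped labels are a candidate explanation. High-risk papilloma 5 was scored on 193 higher and 251 lower genes and low-risk papilloma 6 on 177 and 157. The other tumours had 16 to 56 and 16 to 49, so the scores are not strictly on 1 scale. The score cannot tell a wrong label from a tumour unlike its group. The other low-risk papillomas of the array set of low-risk papilloma 6 scored at most -2.16, which argues against the set as the source of its score. The set of high-risk papilloma 5 held 0 other high-risk papillomas, so for it the set and the tumour cannot be told apart. Without high-risk papilloma 5 the count between the risk groups was 718 and without low-risk papilloma 6 it was 560. On the score from normal skin to carcinoma low-risk papilloma 6 had 1.04, above every high-risk papilloma (0.628 to 0.87). High-risk papilloma 5 had 0.724, within the range of both groups.

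Other splits of the same samples into groups of the same sizes, 100 with the real one, asked how often a split calls as many genes. In 5 comparisons fewer than 5 of 100 did, without adjustment over the comparisons, which makes chance less likely but does not exclude it. High-risk against low-risk papillomas gave 126 genes and 3 splits as many, the highest other 408. Carcinomas against low-risk papillomas gave 212 and 1 split, the highest other 43. Low-risk papillomas against normal skin gave 1427 and 1 split, the highest other 125. High-risk papillomas against normal skin gave 948 and 2 splits, the highest other 2473, and carcinomas against normal skin 219 and 1 split, the highest other 3. For carcinomas against high-risk papillomas chance was not made less likely, since 8 splits gave 8 genes or more and the highest other was 569. Splits that called 408, 569 and 2473 genes point to a structure of the samples other than their groups. Random splits mix the array sets, so this test does not separate group from set.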

How the results depend on the processing

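The fits with the array set as a block, within sets or without the near-identical pair, the score with the set as a term or as a correlation, and list tests after scale normalization were chosen after the results were seen. Unless a value or the construction of an alternative shows it, the cause was not tested.

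Called genes between high-risk and low-risk papillomas (126) were 65 after quantile and 37 after scale normalization, 51 with the range of database number as a block and 1 over arrays of the middle range alone (14382 genes, fewer samples). They were 1250 with array weights and 0 with only the 2 groups in the fit (2180 at an unadjusted p under 0.05). They were 34 with replicate number as a block, though numbers did not pair the samples. They were 0 with the array set as a block (limma, 308 at an unadjusted p under 0.05) and 0 with that block without the pair (210). Between carcinomas and low-risk papillomas (212) they were 116 after scale normalization, 131 over the middle range, 1546 with array weights, 1 with the array set as a block and 1 with that block without the pair. Between carcinomas and high-risk papillomas (8) they were 95 after quantile and 70 after scale normalization, 27 with the database range as a block and 373 with array weights. The count was 1 with only the 2 groups and 0 by limma over probes measured in every sample (691 at an unadjusted p under 0.05), the middle range (1983), the set as a block (451) and that block without the pair (488).

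Between low-risk papillomas and normal skin (1427) they were 604 over the 5583 probes measured in every sample, which are fewer, and 602 with only the 2 groups. The count was 4150 with array weights, 936 with replicate number as a block, 0 by limma over the middle range (1415 at an unadjusted p under 0.05), 5 with the set as a block and 73 with that block without the pair. Between high-risk papillomas and normal skin (948) they were 1794 after quantile and 1572 after scale normalization, 481 over probes measured in every sample and 70 with the database range as a block. It was 0 by limma over the middle range (1003), 3961 with array weights, 12 with the set as a block and 322 with that block without the pair. Between carcinomas and normal skin (219) they were 890 after quantile and 715 after scale normalization, 101 over probes measured in every sample and 19 with the database range as a block. It was 0 by limma over the middle range (387), 691 with only the 2 groups, 3454 with array weights, 10 with the set as a block, 488 without the pair and 141 with the block without the pair. With replicate number as a block the other counts were 167 (carcinomas against low-risk), 7 (against high-risk), 761 (high-risk papillomas against normal skin) and 154 (carcinomas against normal skin).

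Without normalization of the arrays' medians the split of calls between high-risk and low-risk papillomas was 88 higher and 56 lower, after quantile normalization 41 and 24, against 67 and 59. Between carcinomas and low-risk papillomas it was 80 and 111 without centring, 88 and 92 after quantile and 49 and 67 after scale normalization, against 67 and 145. Between carcinomas and high-risk papillomas quantile normalization gave 58 and 37, against 4 and 4. Between low-risk papillomas and normal skin it was 651 and 753 without centring, against 744 and 683. Between carcinomas and normal skin it gave 366 and 524 and scale normalization 274 and 441, against 48 and 171.

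Leaving out 1 replicate at a time gave 60 (without low-risk 1) to 718 (without high-risk 5) genes between the risk groups, and 560 without low-risk 6. It gave 67 without low-risk 5 or high-risk 4, 70, 82, 72 and 77 without high-risk 2, 3, 6 and 9. Carcinomas against low-risk papillomas gave 51 (without carcinoma 3) to 739 (without low-risk 6). It was 126, 90, 138 and 118 without low-risk 1, 5, 8 and 10, and 96, 65, 113, 126 and 129 without carcinoma 1, 2, 4, 5 and 6. Carcinomas against high-risk papillomas gave 0 (limma, without high-risk 2, carcinoma 2 or carcinoma 3, with 1561, 1386 and 1457 at an unadjusted p under 0.05) to 30 (without high-risk 7). It was 4, 5, 2 and 21 without high-risk 1, 3, 4 and 5 and 5, 2 and 16 without carcinoma 1, 4 and 5. Low-risk papillomas against normal skin gave 740 (without normal 3) to 1981 (without low-risk 2), with 935, 865 and 799 without normal 4, 5 and 6. High-risk papillomas against normal skin gave 362 (without normal 6) to 1409 (without normal 1), with 440, 466 and 470 without normal 3, 4 and 5 and 608 without high-risk 3. Carcinomas against normal skin gave 70 (without normal 6) to 549 (without normal 1). It was 119, 145, 128 and 117 without normal 2, 3, 4 and 5 and 92, 126, 96 and 128 without carcinoma 1, 2, 3 and 4.

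Lists that passed between the risk groups were 1 with the set as a block and 1 after scale normalization, against 0. Lists with the block or after scale normalization were tested at the preset correlation only. Between carcinomas and low-risk papillomas (9) they were 1 with an estimated correlation, 5 with fry and 5 with the set as a block. Between carcinomas and high-risk papillomas (12) they were 0 with camera and an estimated correlation (0 of 30, against 12 with a preset one), 4 with fry and 3 with the block. Against normal skin, low-risk papillomas (6) had 1 with an estimated correlation, 11 with fry and 3 with the block. High-risk papillomas (8) had 0 with camera and an estimated correlation and 4 with the block, and carcinomas (13) had 0 with camera and an estimated correlation.

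The difference of the score between the risk groups (0.027) was -0.0565 with the database range as a block, -0.0753 over the middle range, -0.00237 with 1 mean per code, -0.118 with the array set as a term and -0.0665 with that term over called genes. It was 0.0908 over the 219 called genes, 0.0883 over those without muscle, adipocyte, hair follicle and sebocyte genes and 0.0758 over the 488 genes called without the pair. The exact permutation p-values of these were 0.0162, 0.019 and 0.0377. Without the pair it was 0.0289 over all genes (exact permutation p = 0.679). With a correlation in place of the slope, high-risk papillomas had 0.436 and low-risk ones 0.352, a difference of 0.0846 (exact permutation p = 0.176). Leaving out 1 replicate gave -0.034 (without low-risk 2) to 0.0788 (without carcinoma 1), with -0.0209 and -0.0202 without carcinoma 6 and 5. The correlation of the changes against low-risk papillomas (0.583) was 0.205 with the low-risk tumours split.

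Of 141 called results for named genes, 6 stayed called with the array set as a block, 130 did not and 5 changed sign, and without the pair 131 stayed called. The 6 were Rtkn2 in low-risk (-3.36) and high-risk papillomas (-2.46) and Chac2 (-2.82) and S100a9 (5.40) in high-risk papillomas against normal skin, and Chac2 (-2.71) and Ppbp (3.88) in carcinomas against it. With the block Ttll11 (-0.00778), Egln3 (0.309), Snord88c (-0.091), Tbpl1 (-0.117), Btrc (-0.0384) and the uncalled Lcn2 (0.279) changed sign between the risk groups. With the block and without the pair Egln3 (0.197), Snord88c (-0.327), Tbpl1 (-0.0774) and the uncalled Asprv1 (0.0566), Sprr3 (0.00554) and Tgm1 (0.5) did. With the mean over probes Col6a3 was -0.0883 in carcinomas against low-risk papillomas and Ttn -0.111 in high-risk papillomas against normal skin, since the probes of a gene disagreed. Scaling turned 0 of the named genes. Signal over background is not in the deposited values, so its limit is not known here.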

Other observations

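The score of the unlabelled papillomas was chosen after the data were seen and is given as values, without a group for them. The score was the mean of genes higher in high-risk papillomas less the mean of genes lower in them. It used the called genes with a symbol that were found on the second array design, 38 of 49 higher and 33 of 36 lower. The 10 unlabelled papillomas scored -1.18 to -0.134, with a median of -0.836. The labelled papillomas, each scored on genes chosen without it on the first design, ran from -2.23 to 0.142 in the high-risk and from -3.11 to -0.182 in the low-risk group. The designs hold different probes, so the scores of the designs are not on 1 scale.

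Genes of red blood cells were looked at after Hbb-b2 was seen to rise between the risk groups. Of the 8 measured, Hbb-b2 changed by 2.94 and alone passed limma. Bpgm (0.59, adjusted p = 0.47) and Epb42 (0.18, 0.644) were higher. The others, Car2 (-0.74, 0.323), Slc4a1 (-0.63, 0.239), Alas2 (-0.34, 0.631), Hba-a1, an alpha-globin (-0.24, 0.804), and Fech (-0.18, 0.765), were lower.

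Within 1 group, array sets differed too. High-risk papillomas of sets E and C differed by 2320 genes (4 against 4), low-risk papillomas of sets B and D by 298 (6 against 3) and carcinomas of sets C and D by 68 (2 against 4). Arrays of the same set and different groups correlated at a median r of 0.126 after the group means were removed, against -0.0222 for arrays of different sets, across genes, which are not independent replicates.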
